A study of Mus musculus with 2 samples.

How the data were processed

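Exosome RNA from the supernatant of cisplatin-treated LLC cells was profiled on one-colour (Cy3) Agilent mouse miRNA arrays, 1 array for each of 2 samples of a single group. The samples were grouped by their labels. Both arrays lay on the same slide and in the same scan, per the file headers, so no test of slide or scan was possible. The samples came from independent experiments, and whether their preparation formed separate batches was not tested. Per the labels' protocols, the dye was added through a linear-amplification kit for labelled cRNA, whereas the scanner protocol named in the file headers is one for miRNA arrays. Which labelling was used stays open.

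The deposited scanner files hold spot intensities on a linear scale, made with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers. The processed intensity is background-subtracted with spatial detrending within each array, per the file headers, and is not normalized between arrays. It can lie below 0. The files also hold a total signal with its error for each probe and each miRNA, a detection flag per miRNA and flags for outlier and saturated spots. The detection flag was checked on both files: for all 1902 names it was set exactly when at least 1 probe had a total signal over 3 times its error. The authors' deposited value table holds log2 values, whose scale was worked out by comparison with the scanner values. How the authors centred it is not given in the sources used here, and its columns have the same values in sorted order. It was used only as an alternative.

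Spots marked as population outliers were left out, 1069 on array 1 and 1152 on array 2. A miRNA's level was the mean over its probes of the mean over spots of log2 processed intensity, with intensities under 1 set to 1. Each array's 75th percentile over the miRNAs detected on both arrays was subtracted (6.29 on array 1 and 4.58 on array 2), and the mean of both percentiles was added back so that scaled values stay on the original log2 scale. Probes of a miRNA were averaged. On array 2, 82 of the 202 detected miRNAs were detected by only part of their probes, and on array 1, 103 of 312. Negative-control spots, 1000 per array, had a mean intensity of 0.47 with an SD of 2.36 on array 1 and of 1.37 with an SD of 2.81 on array 2, and low signals near these levels carry little information. Control spots were not counted as miRNAs. Names are those of the array design.

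The following were fixed before the data were examined: the detection rule, the scaling, 11 lists of miRNAs (miR-29 family, let-7 family, miR-17~92 and paralogs, p53 and DNA damage, epithelial, tumour-associated, miR-23/27/24 clusters, common reference miRNAs, Dlk1-Dio3 cluster, Sfmbt2 cluster, embryonic stem cell) and 7 marker lists (red cell, leukocyte, stromal, endothelial, hepatocyte, muscle, neural and endocrine). Of 162 names asked for, 160 matched exactly, counting each of the 4 number stems of the Sfmbt2 cluster as a name. miR-106a-5p and miR-486b-5p had no match. The text names the 25 brightest miRNAs detected on both arrays, list members, and the 5 miRNAs farthest apart between the arrays. List examples are the detected members with the highest mean signal, and undetected members are named where there are under 5. A few other names (let-7j, let-7k, miR-34a-5p, miR-503-5p, miR-5100, miR-681, miR-1949, miR-690, the arms of hairpins) were chosen after their values were seen. For each list, 10000 random lists of the same size were drawn from the 1881 miRNAs, and the percent with at least as many detected members is a description of these arrays, not a test. Members of a list can share a hairpin, a transcript or much of their sequence, which random lists do not copy. Whether probes also picked up related members was not tested. The let-7 list holds only 5p arms and the miR-29 list both arms, whereas random lists draw from all names. The percents are therefore not comparable between lists.

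With 1 group there was no comparison between conditions. Alternatives to detection were the majority of spots well above background, a mean intensity over the negative controls by 3 SD, a listed total over 6 times its error, detection on at least 1 array, and each array alone. Alternatives to the levels were normexp background correction with an offset of 50, the listed total signal, the brightest probe, the percentile over all miRNAs, quantile normalization, no scaling, other sets of miRNAs and the authors' value table. The sum of detected probes was added after seeing the data. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp. They were tested on simulated arrays of 1881 miRNAs, where a median SD of 0.202 was built in and 0.196 was recovered, and 4 of 4 checks passed.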

Results

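The data were miRNA profiles of exosomes, small membrane vesicles that cells release, from the culture supernatant of Lewis lung carcinoma (LLC) cells, a mouse lung tumour line. The cells had been kept in serum-free medium with 5 µM cisplatin, a platinum drug that damages DNA, for 24 h. There was 1 group of 2 samples from independent experiments, each hybridised to its own one-colour array, and no untreated group was analysed here. The arrays therefore answer which miRNAs gave a signal in these exosomes and how repeatable that signal was, not what cisplatin changed. Each array carried 58594 spots, of which 56430 belonged to 4415 probes for 1881 mouse miRNAs, and no spot was saturated. With only 2 arrays, the precision of every value below is limited, and no p-values were computed.

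Of the 1881 miRNAs, 201 (10.69%) were detected on both arrays, among them miR-29a-3p, most of the let-7 family, miR-21a-5p and 4 of the 5 miRNAs of the miR-23/27/24 clusters. Array 1 detected 312 miRNAs (16.6%) and array 2 detected 202 (10.74%), so 111 were detected on array 1 alone and 1 on array 2 alone. The count was 312 when array 2 was left out, and 87 when a miRNA had to have the majority of its spots well above background on both arrays.

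miR-29a-3p, the miRNA named in the study's title and a known repressor of collagen mRNAs, was detected on both arrays. Scaling, which removed 1.71 log2 units between the arrays, sets the SDs given with scaled signals from here on. The mean scaled signal of miR-29a-3p was 6.80 ± 0.36 on the log2 scale (SD, n = 2). Before scaling its log2 signal was 7.91 on array 1 and 5.69 on array 2, and the SD between the arrays was then 1.57. Its summed probe signal was 11.7 times its own error on array 1 and 11.1 times on array 2. In the miR-29 family, 2 of the 7 miRNAs on the array were detected on both arrays. The other was miR-29b-3p, with 4.36 ± 0.23 (SD, n = 2). miR-29c-3p was detected on array 1 only, at 3.38 times its error, and the passenger-strand members miR-29a-5p, miR-29b-1-5p, miR-29b-2-5p and miR-29c-5p were detected on neither array. Of 10000 random lists of 7 miRNAs, 16.5% had at least as many detected members. The share detected was 28.6% in the family and 10.69% over all miRNAs. With 7 members, this does not decide whether the family as a whole stood apart from the array.

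Members of the let-7 family share a seed sequence and repress growth-promoting mRNAs such as those of Ras and Hmga2. On both arrays 8 of the 9 listed members were detected, and 0% of 10000 random lists of that size had as many. The listed members are all 5p arms of related sequence, which random lists are not. Also on the array but not on the list were let-7j and let-7k, detected on neither array. Scaled log2 signals were 6.89 ± 0.13 for let-7b-5p, 6.25 ± 0.18 for let-7c-5p and 6.12 ± 0.38 for let-7a-5p (SD, n = 2), and miR-98-5p was not detected. Of the miR-17~92 polycistron and its paralogs, known for their oncogenic role in lymphoma and other tumours, 8 of 12 members were detected, again with 0% of random lists as high. They included miR-20a-5p (5.97 ± 0.08), miR-19b-3p (5.50 ± 0.30) and miR-92a-3p (4.96 ± 0.42). miR-19a-3p was detected on array 1 only, and miR-17-5p, miR-18b-5p and miR-363-3p on neither. The clusters that encode miR-23, miR-27 and miR-24 had 4 of 5 members detected (0.03% of random lists as high), led by miR-24-3p at 6.23 ± 0.29, miR-23a-3p at 5.46 ± 0.32 and miR-27a-3p at 5.38 ± 0.08 (SD, n = 2). miR-27b-3p was detected on array 1 only.

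Among 14 miRNAs known to respond to p53 or to genotoxic stress, 5 were detected on both arrays, and 1.3% of random lists had as many. These were miR-34b-5p (5.40 ± 0.22), miR-34c-5p (5.17 ± 0.07), miR-15a-5p (4.71 ± 0.04), miR-16-5p (4.25 ± 0.08) and miR-22-3p (4.08 ± 0.07) (SD, n = 2). miR-107-3p was detected on array 1 only. miR-34a-5p, a direct transcriptional target of p53, was detected on neither array, with unscaled log2 signals of 0.98 and 0.54. Without an untreated group, detection of these miRNAs says nothing about a response to the drug. Among 10 tumour-associated miRNAs, 4 were detected on both arrays (1.76% of random lists as high). miR-21a-5p, abundant in many carcinomas, had a scaled log2 signal of 7.25 ± 0.08, miR-31-5p of 5.65 ± 0.04, the hypoxia-induced miR-210-3p of 4.64 ± 0.45 and miR-221-3p of 4.39 ± 0.59 (SD, n = 2). Before scaling, miR-21a-5p was 1.82 and miR-31-5p 1.77 log2 units brighter on array 1. Another 5, namely miR-155-5p, miR-222-3p, miR-10b-5p, miR-183-5p and miR-96-5p, were detected on array 1 only, and miR-182-5p on neither. Of 7 miRNAs typical of epithelium, the miR-200 family with miR-203-3p and miR-205-5p, 0 were detected on either array.

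Several miRNAs that are often used as references for normalisation were absent from the detected set. Of 10, 4 were detected on both arrays (1.37% of random lists as high), with miR-25-3p at 4.51 ± 0.09, miR-16-5p at 4.25 ± 0.08 and miR-103-3p at 3.62 ± 0.32 (SD, n = 2). miR-423-5p and miR-26a-5p were detected on array 1 only, and miR-191-5p, miR-423-3p, miR-30c-5p and miR-484 on neither array. The imprinted Dlk1-Dio3 cluster was largely undetected: 2 of 37 members passed on both arrays, miR-494-3p (11.64 ± 0.84) and miR-370-3p (6.46 ± 0.94), and 92.5% of random lists had as many. Of the miRNAs that share a number with the rodent-specific Sfmbt2 cluster (miR-466, miR-467, miR-669 and miR-297), not all of which need lie in it, 11 of 61 were detected (5.37% of random lists as high), including miR-466i-5p at 9.45 ± 0.11, miR-669n at 6.02 ± 0.11 and miR-669l-5p at 4.24 ± 0.07 (SD, n = 2). Of 13 embryonic stem cell miRNAs, 1 was detected, miR-290a-3p at 3.30 ± 1.29, and 76.99% of random lists had as many.

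Markers of other cell types were mostly undetected, with stromal miRNAs as the exception. Of 6 miRNAs typical of fibroblasts and smooth muscle, 4 were detected on both arrays (0.1% of random lists as high): miR-199a-3p (5.90 ± 0.23), miR-199b-5p (4.93 ± 0.24), miR-214-3p (4.26 ± 0.03) and miR-199a-5p (3.02 ± 0.11) (SD, n = 2). Both miR-199a miRNAs are arms under a shared hairpin name, so the 4 are not independent members. miR-143-3p and miR-145a-5p, which mark smooth muscle, were detected on neither array and also stand in the p53 list. Of the 4 red cell miRNAs on the array, miR-451a, miR-486a-5p, miR-144-3p and miR-144-5p, 0 were detected. Of 5 leukocyte miRNAs, miR-142a-3p was detected on array 1 only, and miR-142a-5p, miR-223-3p, miR-150-5p and miR-146a-5p on neither. Detection was 0 of 2 for endothelial miRNAs (miR-126a-3p and miR-126a-5p), 0 of 2 for hepatocyte miRNAs (miR-122-5p and miR-122-3p), 0 of 6 for muscle miRNAs and 0 of 7 for neural and endocrine miRNAs.

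**Figure D1:**
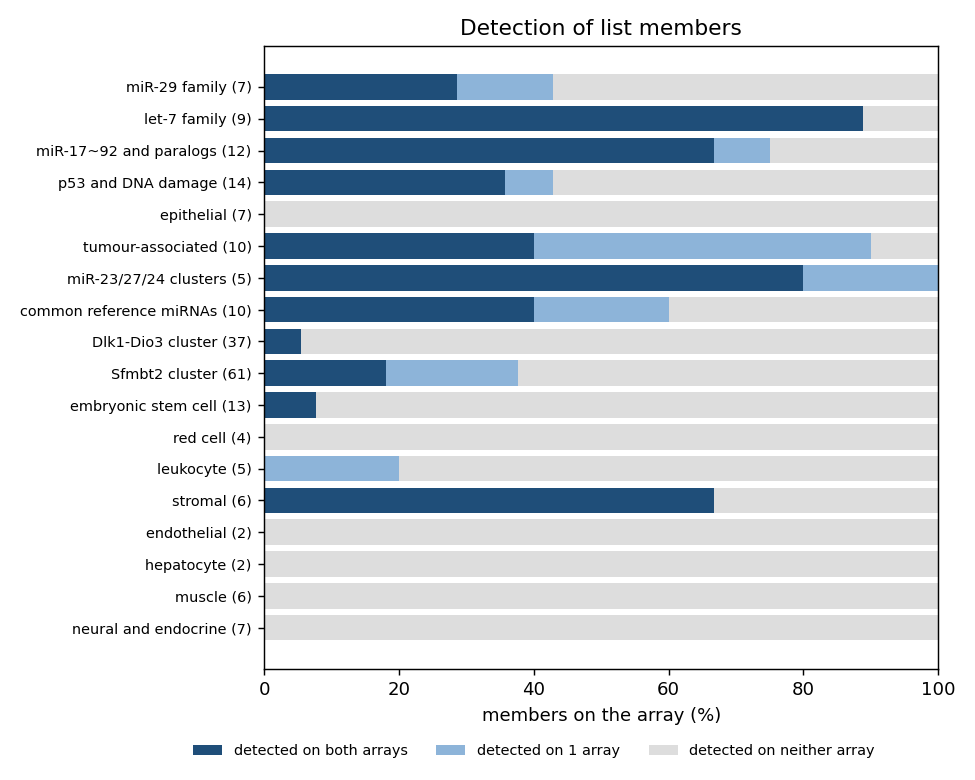
Detection of the members of 18 lists of miRNAs. Bars give the percent of each list's members on the array (number in parentheses) that were detected on both arrays, on 1 array or on neither; let-7 (8 of 9), miR-23/27/24 (4 of 5), miR-17~92 (8 of 12) and stromal miRNAs (4 of 6) had the highest shares on both, and the epithelial, red cell, endothelial, hepatocyte, muscle and neural lists had 0.

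Over all lists, 50 of 212 distinct members were detected on both arrays. In 7 of the 18 lists under 5% of random lists had as many detected members, and the number was 8 when random lists were drawn from miRNAs numbered under 1000, the Sfmbt2 list then lying at 4.77%. These lists overlap. Of the detected reference miRNAs, miR-16-5p also stands in the p53 list, and miR-25-3p and miR-93-5p in the miR-17~92 list. With the majority of spots required to be well above background, detected members fell to 5 for let-7, 4 for the Sfmbt2 list, 2 each for the tumour-associated and stromal lists, 1 each for miR-17~92, the p53 list and the miR-29 family, and 0 for the reference and stem cell lists. Without array 2, 9 tumour-associated and 23 Sfmbt2 list members were detected. The share detected on both arrays was 10.62% of the 819 miRNAs numbered under 1000, let-7 included, and 10.73% of the 1062 numbered 1000 or above. Without array 2 the shares were 19.2% and 14.6%. Arms were paired where their names differed only in 5p or 3p, which gave 723 hairpins with both arms on the array. Names such as let-7f-1-3p, detected on both arrays as was let-7f-5p, were therefore not paired. Of the 723 hairpins, 10 had both arms detected on both arrays, 60 the 5p arm alone, 56 the 3p arm alone and 597 neither. The 10 were let-7b, miR-125a, miR-199a, miR-466h, miR-466i, miR-1897, miR-3102, miR-5132, miR-6769b and miR-7047. This number was 19 without array 2 and 0 when the majority of spots had to be well above background.

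The 25 brightest of the 201 miRNAs had mean scaled log2 signals of 6.89 to 11.64. Brightness depends on the probe, so these signals do not rank the miRNAs by amount. Only 4 of the 25 belonged to a list: miR-494-3p, miR-466i-5p, miR-21a-5p and let-7b-5p. Of the 25, 19 had registry numbers of 1000 or above, including miR-3473b (10.29 ± 0.27), miR-1224-5p (10.03 ± 0.96), miR-6769b-5p (9.50 ± 1.23), miR-8110 (8.92 ± 0.73) and miR-5126 (8.79 ± 0.59) (SD, n = 2). The others numbered under 1000 were miR-574-5p (8.02 ± 0.05) and miR-211-3p (7.10 ± 0.42). The remaining names were miR-1187, miR-3082-5p, miR-3960, miR-3963, miR-5622-3p, miR-6360, miR-6366, miR-6931-5p, miR-6969-5p, miR-7005-5p, miR-7036a-5p, miR-7042-5p, miR-7047-5p and miR-8117. After scaling, the SD between the arrays lay between 0.00053 for miR-1187 and 1.54 for miR-5622-3p. These SDs depend on the scaling and do not rank the miRNAs by repeatability. Before scaling, miR-1187 differed by 1.71, the amount that scaling removed. The unscaled differences, array 1 minus array 2, were only -0.47 for miR-5622-3p and -0.03 for miR-6769b-5p.

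Across the 201 miRNAs, log2 signals of the arrays had a Pearson r of 0.895 and a Spearman rho of 0.797. These are correlations across miRNAs, which are not independent replicates. The median SD between the arrays was 0.67 on the scaled log2 scale, and 98 of the 201 miRNAs lay over 2-fold apart. The miRNAs farthest apart after scaling were miR-8105 (difference of 2.93), miR-125a-3p (2.41), miR-466q (2.41), miR-6388 (2.40) and miR-3095-3p (2.28). Without scaling these 5 differed by 1.21, 0.70, 0.69, 0.68 and 0.57. Quantile normalization left 44 miRNAs over 2-fold apart, and normexp background correction of the mean signals, with an offset of 50, left 3. The offset is added before log2 and draws differences of low signals toward 0. Median unscaled log2 signals of the 201 miRNAs were 4.56 on array 1 and 3.82 on array 2. The 3 is therefore no sign of closer arrays.

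**Figure D2:**
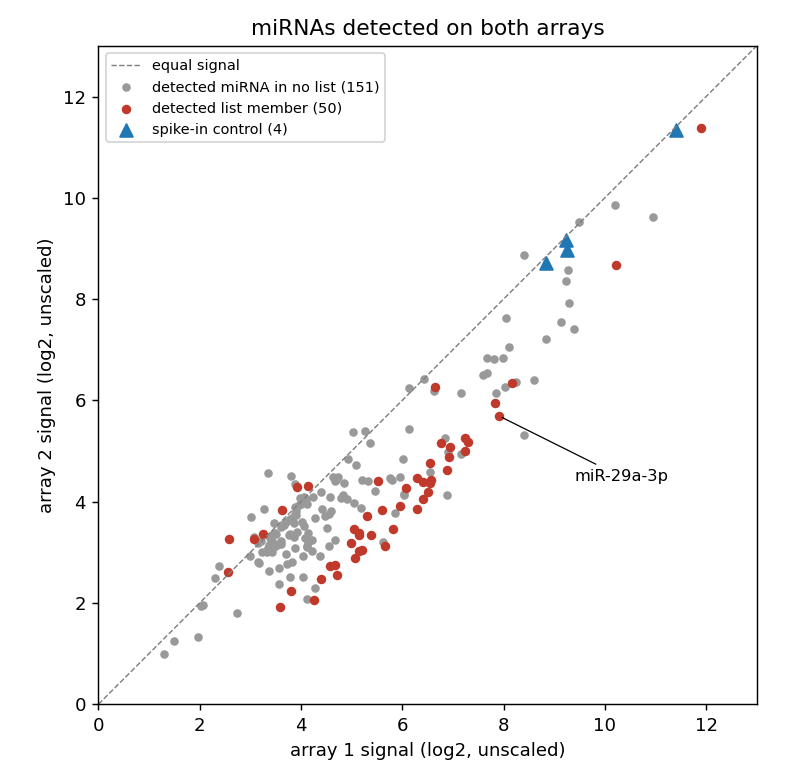
Unscaled log2 signals of the 201 miRNAs detected on both arrays, array 1 on the x axis and array 2 on the y axis. Red points are 50 list members, grey points 151 other miRNAs, blue triangles 4 spike-in controls, and the dashed line marks equal signal; miR-29a-3p lies at 7.91 and 5.69, and the spike-in controls lie close to the line.

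Before scaling, most list members were brighter on array 1 by a similar amount, while the spike-in controls were nearly equal. The 4 detected spike-in controls differed by 0.06 to 0.27 log2 units, with a median of 0.09, array 1 being the brighter. The median difference was 1.86 over the 50 detected list members (interquartile range 1.59 to 2.15) and 0.48 over the 151 detected miRNAs in no list (0.14 to 1.08). For the 8 let-7 miRNAs the median was 2.25, with a range of 1.89 to 2.44. It was 2.13 for the miR-29 family, 2.14 for the miR-23/27/24 clusters, 2.08 for the tumour-associated list, 1.89 for the stromal list, 1.81 for the p53 list, 1.75 for miR-17~92 and paralogs and 1.63 for the reference list. The pair detected in the Dlk1-Dio3 cluster had a median of 0.45, and the Sfmbt2 cluster had a median of -0.06 over members that went both ways. A common scaling factor shifts all of these alike and leaves the gaps between them as they are.

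**Figure D3:**
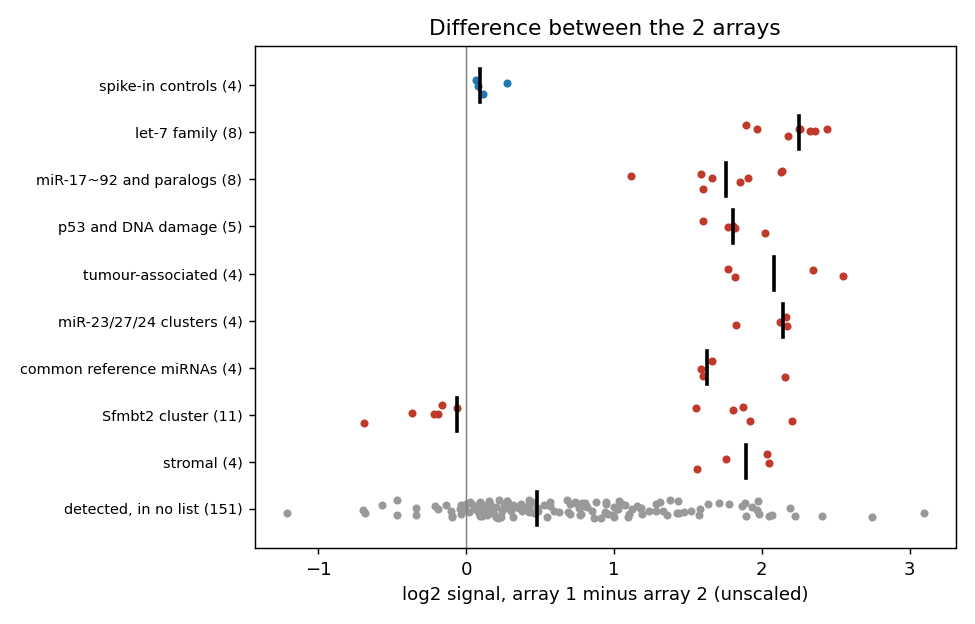
Unscaled log2 signal of array 1 minus array 2, 1 point per miRNA or control, for spike-in controls, for lists with 4 or more detected members and for detected miRNAs in no list. Black bars are medians, 0.09 for the spike-in controls, 2.25 for let-7 and 0.48 for miRNAs in no list; in the Sfmbt2 cluster 5 members lie between 1.55 and 2.20 and 6 lie below 0.

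The authors' value table was set against the scanner values to find its scale. Its 2 columns hold log2 values, with identical values in sorted order, a lowest value and median of -3.32 and a highest value of 13.25. Across detected miRNAs its Pearson r with the log2 of the total signal listed per miRNA was 0.459 on array 1 and 0.666 on array 2. Against the sum of each miRNA's detected probes, an alternative chosen after seeing the data, r was 0.949 and 0.994, and Spearman's rho was 1 on both arrays. In the column of array 2, 111 of the 322 values above the lowest belonged to names not detected on that array, so a value above the lowest is not a detection call. The distribution both columns share differs from the mean of these arrays' own log2 sums by up to 2.22, and its origin stays unknown.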

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

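The tests in this part were all chosen after the results were seen, and no biological explanation was tested, since the design has 1 group. Control names outside the miRNA measurement gave signals far above the negative controls, whose mean plus 3 SD corresponds to log2 signals of 2.92 on array 1 and 3.29 on array 2. Mean unscaled log2 signals were 16.29 for hur_2, 12.84 for hur_1, 12.69 for mr_1, 9.65 for hur_4 and 9.54 for hur_6. Another of these names, hur_5, was detected on neither array (0.55 and 0.47). What the names stand for is not given in the sources used here. The detected ones were brighter on array 1, by 0.74 (hur_2), 1.01 (mr_1), 1.22 (hur_1), 1.25 (hur_4) and 2.83 (hur_6), while the 4 spike-in controls differed by at most 0.27.

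Array 1 was brighter than array 2 for part of the miRNAs only. The 4 spike-in controls argue against a weaker hybridization or scan of the whole array 2. They differed by at most 0.27, below the lower quartile of the list members (1.59). At which step they were added is not given in the sources used here, so a weaker labelling of array 2 stays open. Other controls go the other way: the detected hur and mr_1 controls were brighter on array 1 by 0.74 to 2.83. The control miRNABrightCorner30 does so too, with log2 signals of 3.65 on array 1 and 1.19 on array 2, where it was not detected. List members with a mean log2 signal under 6 still differed by a median of 1.84, so their differences were not compressed toward 0. The cut at 6 lies above the negative-control limits of 2.92 and 3.29. Under it, list members had a median mean signal of 4.26 and miRNAs in no list 3.68. The sets are thus not matched, and these values cannot decide whether compression of dim signals near the background made the sets differ. For miRNAs in no list compression stays open: the dim ones differed by a median of 0.38 and those at 6 or more by 1.11, a gap of 0.73. Of the 52 detected miRNAs that differed in size by no more than the highest spike-in control, 49 had a mean signal under 6. Among the other 149 detected miRNAs 114 did. Signal at some probes that may not follow the amount of RNA also stays open, since probes of one miRNA disagreed by a median of 0.19 among the 52 and 0.16 among the other 149. A different amount of sample RNA and a different mix of miRNAs in the exosome preparations were not tested and cannot be told apart here.

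The total signal that the scanner files list per miRNA differed by over 1% from the sum of the miRNA's own detected probes for 89 of 322 detected names on array 1 and 60 of 211 on array 2. A carry-over is a candidate explanation: all 149 such totals equalled the own sum plus the listed total of the detected name just before in alphabetical order, within 1%. They were exactly the names whose first probe was not detected, and 0 of the 233 and 151 names with a detected first probe differed. Real signal of the miRNA's own probes is argued against by 147 of the 149 totals that lay above the sum of all positive probe totals. On array 1, miR-503-5p was listed at 1773 against 3.10 from its own probes, after miR-494-3p, and on array 2 miR-5100 was listed at 1261 against 13.5 and miR-681 at 313 against 1.20.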

How the results depend on the processing

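Replacing listed totals by sums of detected probes was chosen after seeing the data, and all other alternatives were planned. No paired analysis was possible because there was only 1 group. Counts of detected miRNAs moved with the level of signal over background required. Detected on both arrays were 201 miRNAs, against 87 with the majority of spots well above background, 313 on at least 1 array, 117 with the own probe sum over 6 times its error, and 202 to 312 with 1 array left out. Detected list members, 50, became 21 and 33 with the majority of spots and the own probe sum and 50 to 74 with 1 array. Hairpins with both arms, 10, became 0 (majority of spots), 6 (negative controls), 4 (listed totals), 19 (at least 1 array), 1 (own probe sum) and 10 to 19 (1 array). Detection under and from number 1000 moved from 10.62% and 10.73% to 4.52% and 4.71% (majority of spots), 7.94% and 8.66% (negative controls), 8.67% and 7.34% (listed totals), 19.2% and 14.7% (at least 1 array), 6.47% and 6.03% (own probe sum), and with 1 array to 10.6% to 19.2% and 10.8% to 14.6%. Pearson r, 0.895, moved to 0.706 with listed totals, 0.941 over all miRNAs and 0.830 with the authors' table. With own probe sums it was 0.879, so the fall to 0.706 came with the carried totals. The median SD, 0.67, moved to 0.39 with normexp, 0.42 with the percentile over all miRNAs and 1.18 over all miRNAs. The 98 miRNAs over 2-fold apart became 3 with normexp, 44 after quantile normalization, 1603 of 1881 over all miRNAs and 33 of 87 with the majority of spots well above background. The offset of 50 in normexp draws differences of low signals toward 0. Of the 1881 miRNAs, 1568 were detected on neither array, and the scaling shift of 1.71 alone sets equal unscaled signals over 2-fold apart. The 1603 and the median SD of 1.18 therefore do not measure repeatability. The level of miR-29a-3p, 6.80, was 7.60 with normexp, 5.99 with listed totals and with own probe sums, 7.96 for its brightest probe, 5.73 in the authors' table and 5.69 to 7.91 with 1 array, values on different scales. The r of the authors' table rose from 0.459 and 0.666 to 0.949 and 0.994 with own probe sums, which differ from listed totals by over 1% only for the 89 and 60 names with carried totals. Beyond these points the cause was not tested. Of 74 alternatives to these results 43 moved them and 31 did not, and for single lists 21 of 144 moved a count and 1 took the Sfmbt2 list from 5.37% to 4.77% of random lists.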

Other observations

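The tests behind this part were chosen after the data were seen. The miRNAs numbered as in the Sfmbt2 cluster, a large rodent-specific group of related miRNAs, differed between the arrays in both directions. Of the 11 detected on both, 5 were brighter on array 1 by 1.55 to 2.20 log2 units before scaling, namely miR-466i-5p, miR-669l-5p, miR-669e-5p, miR-466h-5p and miR-669n. The other 6, miR-466f-3p, miR-466h-3p, miR-466i-3p, miR-466q, miR-467f and miR-669p-3p, were brighter on array 2, with differences of -0.69 to -0.06. After scaling by the 75th percentile, which moved the arrays by 1.71, the 5 lay close together between arrays and the 6 apart. Of the 6, miR-466f-3p, miR-466h-3p, miR-466i-3p and miR-669p-3p differed before scaling by no more than the highest spike-in control (0.27). Array 2 signals under the negative-control limit of 3.29 occurred in both sets, as for miR-466h-5p (2.06) and miR-466f-3p (2.62). By the negative-control rule 8 of the 11 stayed detected, and 4 by the majority of spots. The split thus rests partly on signals near background. It also ran with the arm: every name ending in 5p was in the set brighter on array 1, and every name ending in 3p in the other. The reason was not tested.

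Arms of one hairpin, which are cut from the same precursor, also had unlike array differences, though partly at signals near background. Of the 10 name-matched hairpins with both arms detected, 5 had arms whose array differences lay over 1 log2 unit apart. In all 5 the 5p arm had the higher difference, array 1 minus array 2. For let-7b the differences were 1.89 (5p) and 0.20 (3p), for miR-466h 2.20 and -0.16, for miR-466i 1.55 and -0.19, for miR-125a 1.02 and -0.70, and for miR-3102 1.07 and -0.21. Each of these 5 had an arm with an array 2 signal at or under the negative-control limit of 3.29. These arms were let-7b-3p (3.23), miR-466h-5p (2.06), miR-466i-3p (3.26), miR-125a-5p (2.81) and miR-3102-3p (3.29). With the majority of spots required to be well above background, 0 hairpins kept both arms. The gaps therefore do not show that the arms behaved differently. In miR-199a both arms were brighter on array 1, by 1.56 (5p) and 2.03 (3p), and in miR-6769b the arms differed by -0.03 and -0.03. The unpaired let-7f-5p and let-7f-1-3p were brighter on array 1 by 2.44 and 0.10, with an array 2 signal of 3.29 for let-7f-1-3p.

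A difference of 1.5 to 2.5 log2 units was found for 39 of the 50 detected list members and 18 of the 151 other detected miRNAs. Of the 52 miRNAs that differed in size by no more than the highest spike-in control, 38 had numbers of 1000 or above and 5 belonged to a list. The highest differences in favour of array 1 were those of miR-1949 (3.09) and miR-690 (2.74), and the highest in favour of array 2 was that of miR-8105 (-1.21). miR-17-5p, whose precursor lies in the same transcript as those of the detected miR-20a-5p and miR-19b-3p, had unscaled log2 signals of only 0.55 and 0.15.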
